A study of Homo sapiens with 24 samples.

How the data were processed

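The series holds 24 Affymetrix arrays of CD133+ cells sorted from peripheral blood of 4 healthy subjects and of 10 patients with coronary artery disease, sampled at baseline and after 3 months of exercise. Groups were taken from the sample labels, and the series' design text states that the same patients were sampled at both times. Per the labels' protocols, total RNA was extracted from the sorted cells with a micro-scale kit and biotin-labelled by in vitro transcription. Per the submitters' processing notes MAS5 was used; the transformation, the filter on probe sets and any later normalization are not given in the sources used here.

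One table of 26123 probe sets was used. Its values are a deposited score with no stated unit: each of the 24 arrays holds the identical set of 26123 distinct values between 0 and 4.51 (median 0.687), so that the value of a probe set depends only on its rank on its array and the table was already quantile-normalised as deposited by the authors. The design fixed before the data were examined had assumed log2 values or linear MAS5 intensities. As the unit turned out to be a score, limma was run on the scores as deposited, without a further transformation. A scale for the score was sought in the bacterial hybridization controls bioB, bioC and bioD, nominally at 1.5, 5 and 25 pM. Their slope was 0.99 ± 0.171 score units per 10-fold (SD, n = 24 arrays, range 0.508 to 1.34) over scores of 0.984 to 3.9, which is close to a log10 scale there; for lower scores the scale stays unknown. Since every array was forced to the same values, a shift of most genes in one direction cannot be seen, and a higher score of one gene lowers the rank of others.

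Probe sets were named through the platform annotation, with symbols updated by gene identifier: 20524 had 1 gene symbol, 1022 had several and 4544 had none, and 33 were control probe sets. Of those with 1 symbol, 14 had no match in the reference gene table and kept the file's symbol. Probe sets with several symbols or none were not tested, and 52 probe sets of sex-linked genes were left out. Probe sets in the lower 50% by mean score over all arrays (under 0.642) were left out, and each gene was represented by its probe set with the highest mean, which left 7264 of 11721 genes. Of these probe sets 2792 are of the designs that can detect more than 1 transcript or family member, so their values can include related transcripts.

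Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, between CAD baseline and healthy, between CAD after exercise and healthy, and between CAD after exercise and CAD baseline. In the exercise comparison the patient was a fixed block, since the 10 pairs come from the same patients; the fit without the replicate block gave 0 genes, as the paired fit did, and 285 genes at an unadjusted p under 0.05. As a check of the pairing, the deviations from the group means of a patient's 2 arrays had a mean correlation of 0.194 (from -0.179 to 0.675, over 0.1 in 4 of 10 pairs), against -0.019 for arrays of different patients. No pair of arrays was duplicated (highest correlation 0.951). On simulated data with 200 of 7264 genes changed, the baseline comparison recovered 56% of changes of 0.5 units and 99% of changes of 1 unit. The exercise comparison recovered 89% and 100%, and the comparison after exercise with healthy subjects 60% and 100%. The noise was drawn independently for each gene, without correlation between genes or shifts of whole arrays, so that recovery on the real arrays can differ. The largest named change with exercise, 0.432, was smaller than the sizes simulated, so that recovery at its size is unknown.

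A total of 30 gene lists (cell types of blood, sorted progenitors, and processes such as apoptosis, cell cycle and metabolism) had been fixed before the data were examined. Of these, 25 had at least 5 measured members and were tested with camera (preset correlation 0.01), adjusted over the lists. The remaining 5 (granulocyte-monocyte progenitor, endothelial, neutrophil, B cell and erythroid) had 3 or 4 and were not tested: their mean differences between baseline and healthy were 0.0849, 0.15, 0.0621, -0.298 and -0.143 units. Measured members are those among the 7264 genes tested, which were 18 of the 25 listed for stem and progenitor cells. CD34, on that list, and KDR, on the endothelial list, were not among the genes tested. As further tests, camera with an estimated correlation, fry, and an exact permutation of each array's mean list score (added after seeing the data) were run. Named genes followed a rule fixed in advance: as no gene passed, the 6 with the smallest p in each direction, plus the 3 members with the smallest p of each list called by camera, and the first 2 measured members of 6 cell type lists as level checks; genes that vary in copy or sequence between people and unnamed loci were excluded. Measures of RNA quality were compared by exact permutation tests. Alternatives covered centring, filters, probe set summaries, variance models, array weights, covariates, the samples in the fit, the threshold and leaving out each subject; covariates for the spike-in level and the progenitor score, normal scores, median centring for the gene lists, and leaving out arrays with a mean correlation under 0.7 were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.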

Results

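CD133+ cells, a fraction enriched for circulating stem and progenitor cells, had been sorted by fluorescence from 32 ml of peripheral blood, and their RNA was measured on 24 expression arrays. The study had no patients without exercise, so that a change with exercise and one with time alone are not separated. The arrays came from 4 healthy subjects, from 10 patients with coronary artery disease (CAD) at baseline, and from the same 10 patients after a cardiac rehabilitation program of 36 exercise sessions of 60 minutes over 3 months. Levels are given in the deposited score, which ran from 0 to 4.51 with a median of 0.687 on every array. Over the range covered by the bacterial spike-in controls, a 10-fold difference in concentration corresponded to 0.99 ± 0.171 score units (SD, n = 24 arrays), so that 0.5 units stood for roughly a 3.2-fold difference there. The scale of lower scores is unknown. Differences are therefore given in score units and not as folds. The 4 healthy arrays limit the precision of the comparisons with healthy subjects: the median SE of a difference was 0.118 units at baseline and 0.129 after exercise, against 0.0827 for the exercise comparison. After dim probe sets had been left out, 7264 genes were tested.

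Control measures were compared between groups, and none of 12 tests passed the adjusted threshold (lowest adjusted p = 0.216). The spike-in level, the mean score of 7 bacterial control probe sets added in fixed amounts, was 3.12 ± 0.363 (SD, n = 4) in healthy subjects, 2.43 ± 0.446 (n = 10) in patients at baseline and 2.71 ± 0.591 (n = 10) after exercise. The difference between baseline and healthy subjects was -0.690 (exact permutation test, two-sided p = 0.018; adjusted p = 0.216 over 12 such tests). The difference between the 3' and 5' probe sets of GAPDH, a measure of RNA integrity, was 0.944 ± 0.487 (n = 4) in healthy subjects, 1.11 ± 0.308 (n = 10) at baseline and 1.23 ± 0.343 (n = 10) after exercise. It was 0.119 higher after exercise than before (exact sign-flip permutation test, p = 0.0371; adjusted p = 0.223). The same measure for ACTB was 0.320 lower in patients at baseline than in healthy subjects (exact permutation p = 0.0859; adjusted p = 0.262) and differed by 0.0087 between the patients' samples (p = 0.957).

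**Figure D1:**
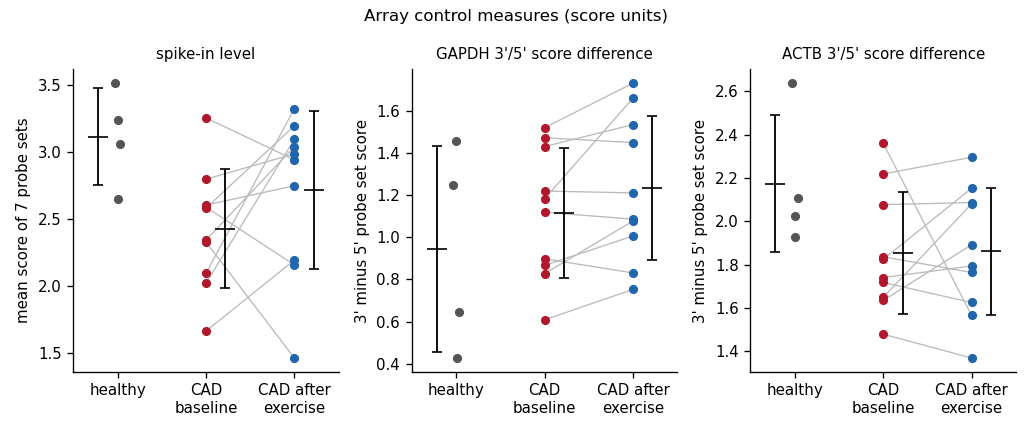
Spike-in level, GAPDH 3' minus 5' score and ACTB 3' minus 5' score, in score units, for each array of 4 healthy subjects and 10 CAD patients at baseline and after exercise. Points are arrays, grey lines join the arrays of one patient, and black bars give the mean and SD. The spike-in level averaged 3.12 in healthy subjects and 2.43 in patients at baseline, with overlapping ranges.

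The first comparison asked how cells sorted as CD133+ from patients at baseline differed from those of healthy subjects. The 6 transcripts with the smallest p among those higher in patients included TSC22D1, a leucine zipper protein of the TGF-beta response, with a score of 2.18 ± 0.311 (SD, n = 10) against 1.14 ± 0.553 (n = 4), and POLB, the DNA polymerase of base excision repair, 0.674 ± 0.135 units higher (difference ± SE). BST2, the interferon-inducible tetherin, was 0.535 ± 0.109 higher. The others were HSD17B10, a mitochondrial dehydrogenase, 0.489 ± 0.096 higher, STAT3, a transcription factor of cytokine signalling, 0.482 ± 0.097 higher, and PARVB, the focal adhesion protein beta-parvin, 0.465 ± 0.0886 higher. Each was above the healthy mean in 10 of 10 patients. The corresponding lower transcripts were SERPINB9, an inhibitor of granzyme B, by -0.621 ± 0.145 units, PRKCA, protein kinase C alpha, by -0.469 ± 0.111, and SRPK2, a kinase of splicing factors, by -0.432 ± 0.0924. They also included the nuclear body protein SP100 by -0.408 ± 0.0952, the Elongator subunit ELP2 by -0.359 ± 0.0847, and the pseudogene RABGEF1P1 by -0.331 ± 0.0754. No gene passed the adjusted threshold of 0.05 with limma. The adjusted p of the 6 higher genes and of SRPK2 was 0.0987, and that of the other lower genes was 0.112. At an unadjusted p under 0.05 limma gave 888 genes, 660 higher and 228 lower in patients, where 363.2 would be expected by chance. After centring each array on its median, 477 of 822 such genes were higher. With the spike-in level as a covariate there were 580, 336 higher and 244 lower. With the progenitor score as a covariate there were 773, 517 higher and 256 lower. Without 1 of the healthy subjects, 26 genes passed the adjusted threshold. Of the probe sets above the filter, 1 of 2 for PARVB, SRPK2 and SERPINB9, 2 of 3 for ELP2 and 3 of 4 for SP100 differed in the direction given. With the mean of a gene's probe sets the difference was 0.218 for PARVB (adjusted p = 0.451), 0.253 for STAT3 (0.267), -0.191 for SRPK2 (0.386), -0.153 for SERPINB9 (0.559), -0.0801 for ELP2 (0.824) and -0.292 for SP100 (0.214).

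In the stem and progenitor cell list, 18 of 18 measured members had higher means in patients than in healthy subjects, with a mean difference of 0.335 units (camera, adjusted p = 8.60e-04; adjusted p = 0.904 with an estimated correlation). PROM1, which encodes CD133, the antigen used for sorting, had a score of 0.355 ± 0.240 (SD, n = 4) in healthy subjects and 1.20 ± 0.603 (n = 10) in patients at baseline. The healthy mean lies below 0.642, the limit under which probe sets were left out as dim, and the labels give no purity of the sorts. The receptor tyrosine kinase FLT3 was 0.458 ± 0.166 units higher (SE) and the ligand ANGPT1 was 0.490 ± 0.183 higher (0.297 with the mean of its 2 probe sets, adjusted p = 0.48). The mean score of the list was 0.685 ± 0.0537 (SD, n = 4) in healthy subjects and 1.02 ± 0.325 (n = 10) in patients, of whom 7 of 10 lay above the healthy mean (exact permutation p = 0.0749; adjusted p = 0.268 over 25 lists). Of the platelet and megakaryocyte list, 13 of 14 members were higher (mean difference 0.256, camera adjusted p = 0.00275; adjusted p = 0.904 with an estimated correlation; exact permutation p of the array scores 0.041, adjusted p = 0.256). P-selectin (SELP) was 0.366 ± 0.102 units higher, clusterin (CLU) 0.328 ± 0.127 (0.199 without 1 of the healthy subjects and 0.178 with the spike-in covariate) and platelet factor 4 (PF4) 0.321 ± 0.129. Neither list had a member past the threshold over all genes tested; adjusted over the list alone, 0 progenitor genes and 1 platelet gene passed. Among other cell types, the mean difference was -0.0741 for 18 monocyte genes, -0.0743 for 8 T cell genes and 0.161 for 14 NK cell genes, of which 14 were higher (camera adjusted p = 0.318, 0.318 and 0.337), and the spike-in level, as given above, was lower in the patients. With the spike-in level as a covariate the platelet call was lost (adjusted p = 0.0927). The remaining lists did not pass, with the lowest adjusted p being 0.0734.

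**Figure D2:**
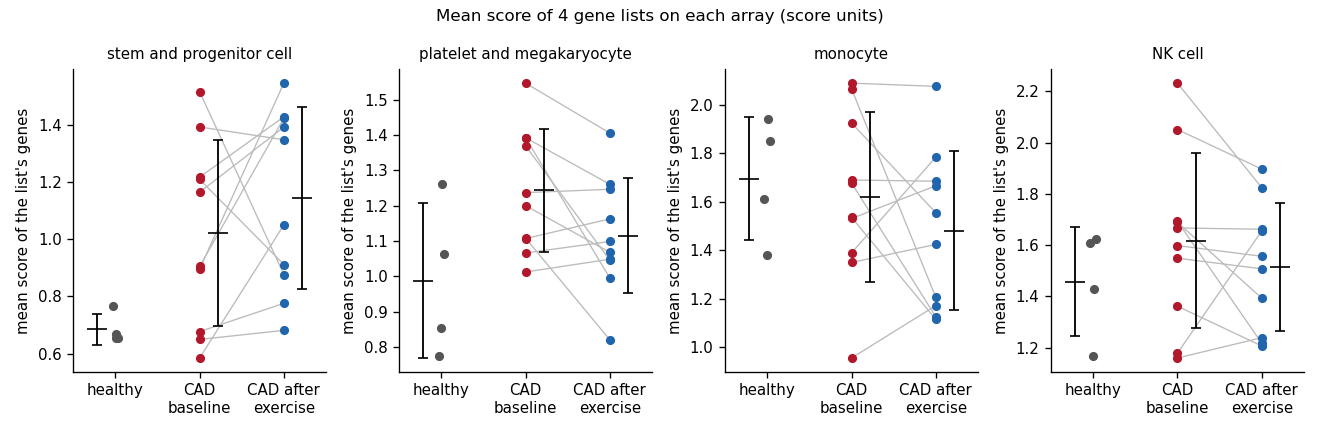
Mean score of the measured genes of 4 lists (stem and progenitor cell, platelet and megakaryocyte, monocyte, NK cell), in score units, on each of the 24 arrays. Points are arrays, grey lines join the baseline and after-exercise arrays of one patient, and black bars give the mean and SD. The progenitor score was 0.685 ± 0.0537 in the 4 healthy subjects and spread from 0.585 to 1.52 in the patients at baseline.

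The second comparison asked which transcripts changed in the patients over the 3 months of exercise. The genes with the smallest p that were higher after exercise were TAF5, a subunit of the general transcription factor TFIID, by 0.432 ± 0.117 units (SE), ERCC6L2, a DNA repair helicase, by 0.366 ± 0.0966, the interferon receptor subunit IFNAR2 by 0.287 ± 0.0828, UBXN10 by 0.249 ± 0.0761, the splicing-related LUC7L3 by 0.236 ± 0.0587 and the microtubule-affinity kinase MARK4 by 0.225 ± 0.0668. Each differed in this direction in 8 or 9 of the 10 patients. Of the 3 probe sets of IFNAR2, 2 changed in this direction, and the mean of the 3 changed by 0.076 (adjusted p = 0.861). The lower ones were the kinase MAP3K13, by -0.416 ± 0.103 and in 10 of 10 patients, OSGEPL1 by -0.365 ± 0.0978, VNN2, a leukocyte surface vanin, by -0.306 ± 0.0815, the cytoskeletal vinculin VCL by -0.278 ± 0.0766, SH3BGRL3 by -0.274 ± 0.0731 and ARPC3, a subunit of the actin-branching complex, by -0.236 ± 0.0592. None passed: the paired limma fit gave 0 genes at an adjusted p under 0.05, the lowest adjusted p was 0.804, and 436 genes had an unadjusted p under 0.05, of which 149 were higher and 287 lower (363.2 expected by chance). After centring each array on its median 185 were higher and 246 lower, and with the spike-in level as a covariate 325 were higher and 348 lower. Without the replicate block there were again 0 genes and 285 with an unadjusted p under 0.05.

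Lists were called by camera in 5 cases, each with an adjusted p of 0.609 with an estimated correlation. That correlation between members was 0.563 for the progenitor, 0.608 for the monocyte, 0.522 for the NK cell, 0.185 for the platelet and 0.19 for the inhibitor list. In the stem and progenitor cell list 15 of 18 members were higher after exercise (mean 0.122 units, adjusted p = 0.00147), among them the receptor KIT, 0.246 ± 0.124 higher (SE), the cell cycle kinase CDK6, 0.260 ± 0.145, and the transcription factor ERG, 0.185 ± 0.126. In the monocyte list 18 of 18 members were lower (mean -0.14, adjusted p = 0.00224), with thrombospondin (THBS1) at -0.300 ± 0.0966 (-0.14 with the mean of its 3 probe sets), MS4A7 at -0.224 ± 0.105 and the scavenger receptor CD36 at -0.256 ± 0.121. The platelet and megakaryocyte list had 13 of 14 members lower (mean -0.128, adjusted p = 0.00224), with neurogranin (NRGN) at -0.323 ± 0.1, PF4 at -0.217 ± 0.0916 and PF4V1 at -0.228 ± 0.117. In the NK cell list 13 of 14 were lower (mean -0.102, adjusted p = 0.0243), including granzyme A (GZMA) at -0.250 ± 0.0846, NKG7 at -0.171 ± 0.09 and the receptor KLRD1 at -0.170 ± 0.0924. In the cell cycle inhibitor list 8 of 9 were lower (mean -0.0941, adjusted p = 0.0243), with the pocket protein RBL2 at -0.171 ± 0.0737, CDKN1A at -0.159 ± 0.0979 and CDKN1B at -0.0978 ± 0.0658. Of the 2 probe sets of RBL2, 1 changed in the opposite direction, and their mean changed by -0.0197. Without 1 patient the change was as small as 0.16 for KIT, 0.127 for CDK6, 0.095 for ERG, -0.159 for CD36, -0.145 for PF4V1, -0.105 for NKG7, -0.0982 for KLRD1, -0.0683 for CDKN1A and -0.0531 for CDKN1B. Of the 27 named changes with exercise, 19 became smaller by over 1.5 times with array quality weights and 12 with the GAPDH covariate. With the spike-in level as a covariate CDK6 (0.428) and ERG (0.33) became larger by over 1.5 times, and 7 lists were called (adjusted p = 8.49e-09 for the progenitor, 4.54e-06 for the monocyte and 2.67e-04 for the platelet list). No member of these 5 lists passed over all genes or adjusted over the list alone. Tested on the 10 patients' changes in list score, the exact sign-flip permutation p was 0.342 for the progenitor list (higher in 7 of 10 patients), 0.293 for monocyte genes, 0.0352 for platelet genes, 0.25 for NK cell genes and 0.0508 for the inhibitors, with adjusted p of 0.475 to 0.57. The GAPDH 3' to 5' difference was higher after exercise in 6 of 10 patients (adjusted p = 0.223, as given above). With it as a covariate the progenitor list turned in direction (adjusted p = 0.826) and the monocyte (adjusted p = 0.0871), NK cell (0.991), platelet (0.42) and inhibitor (0.467) calls were lost. Leaving out arrays that stand apart from the others, with their patients, ended the progenitor (adjusted p = 0.13), monocyte (0.286), NK cell (0.259) and inhibitor (0.305) calls. Leaving out 1 patient raised the adjusted p to as much as 0.0988 for the progenitor list, 0.43 for monocyte, 0.287 for NK cell, 0.0961 for platelet and 0.145 for inhibitor genes.

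The third comparison set the patients after exercise against the same healthy subjects. PROM1 was 1.11 ± 0.241 units higher in the patients (SE; 1.47 ± 0.574 (SD, n = 10) against 0.355 ± 0.240 (n = 4)) and TSC22D1 1.07 ± 0.225 units higher. CPED1 was 0.737 ± 0.142, POLB 0.652 ± 0.142, the ferric reductase CYBRD1 0.50 ± 0.105 and PARVB 0.459 ± 0.102 units higher, each in 10 of 10 patients. For PARVB the mean of its 2 probe sets differed by 0.196, and for SERPINB9, given next, by -0.222. Among the lower genes were MS4A1, the B cell antigen CD20, at -0.837 ± 0.214, SERPINB9 at -0.732 ± 0.189, the lymphocyte receptor LY9 at -0.716 ± 0.142, PRKCA at -0.574 ± 0.146, the RNA-binding protein RBM47 at -0.477 ± 0.129 and the Golgi adaptor GGA2 at -0.458 ± 0.111. With limma 0 genes had an adjusted p under 0.05 (lowest 0.17) and 713 an unadjusted p under 0.05, of which 525 were higher and 188 lower. After centring each array on its median, 413 of 678 such genes were higher, and without the filter on dim probe sets 664 of 1030. With the progenitor score as a covariate there were 408, 258 higher and 150 lower, where 363.2 would be expected by chance. At baseline this covariate had left 773. The progenitor score itself differed between patients and healthy subjects, by 0.335 units at baseline and 0.458 after exercise. As a covariate it therefore takes up part of the group difference, more so after exercise. The counts cannot show whether progenitor content accounts for the differences. After exercise the covariate brought the difference to 0.639 for TSC22D1 and 0.407 for CPED1. Without 1 of the patients, 4 genes passed the adjusted threshold.

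The progenitor list again had 18 of 18 members higher (mean 0.458 units, camera adjusted p = 3.64e-11, and 0.891 with an estimated correlation, which was 0.56). They included PROM1, ANGPT1 (0.626 ± 0.151) and the transcription factor MEIS1 (0.715 ± 0.189). Adjusted over the list alone 8 of the 18 passed, and 0 did over all genes. The array scores gave an exact permutation p of 0.012 (adjusted p = 0.3), with 9 of 10 patients above the healthy mean. Of the monocyte list 17 of 18 members were lower (mean -0.214, adjusted p = 1.94e-04; adjusted p = 0.893 with an estimated correlation; exact permutation p = 0.262), with MNDA at -0.412 ± 0.176, versican (VCAN) at -0.540 ± 0.247 and the lectin CLEC7A at -0.277 ± 0.143. With the progenitor score as a covariate VCAN (0.0591) and CLEC7A (0.00236) turned in direction and MNDA was at -0.0145. The mean of the 3 probe sets of VCAN differed by -0.342. Of the pro-apoptotic list 13 of 17 members were lower (mean -0.0835, adjusted p = 0.0496; adjusted p = 0.893 with an estimated correlation; exact permutation p = 0.183), among them BCL2L11, the BH3-only protein BIM, at -0.372 ± 0.142 (-0.18 with the mean of its 5 probe sets), the death receptor TNFRSF10B at -0.248 ± 0.152 (-0.161 without 1 of the patients) and its ligand TNFSF10 at -0.202 ± 0.125 (in this direction in 1 of 3 probe sets, whose mean differed by 0.00632). With the progenitor score as a covariate the differences were -0.198 for BCL2L11, -0.0734 for TNFRSF10B and -0.00946 for TNFSF10. In these fits too, the covariate itself differed between the groups. With the spike-in level as a covariate the monocyte and pro-apoptotic calls were lost (adjusted p = 0.118 and 0.0864). Without 1 of the healthy subjects the adjusted p was 0.0615 for the monocyte and 0.41 for the pro-apoptotic list.

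**Figure D3:**
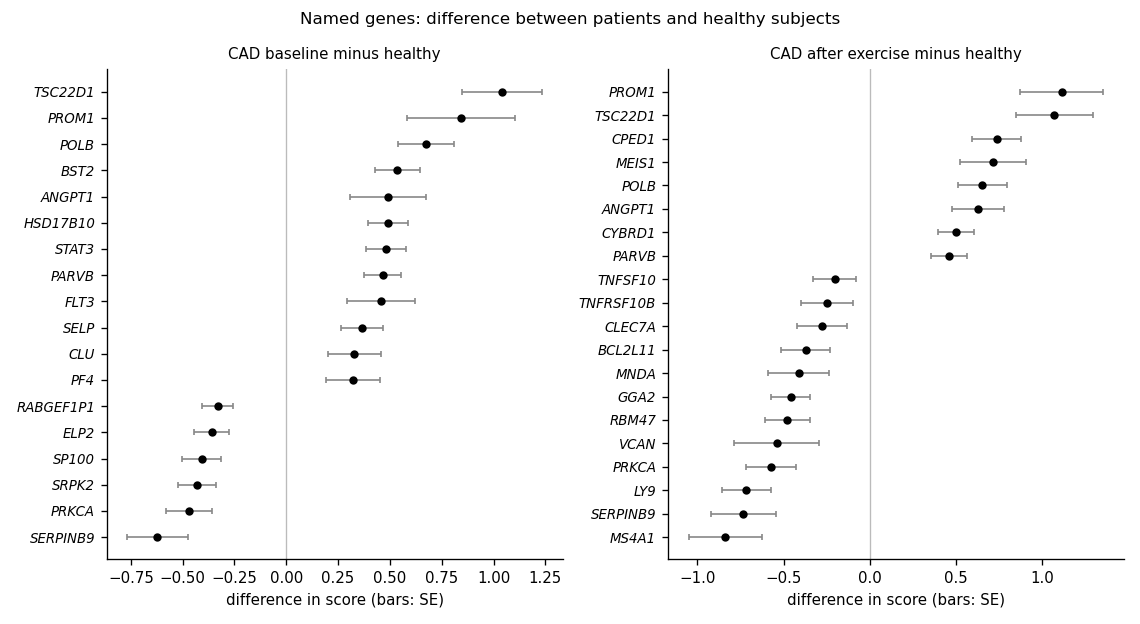
Differences in score (patients minus healthy subjects) of the named genes at baseline and after exercise; points are limma estimates and bars are SE (10 patients against 4 healthy subjects). TSC22D1 and PROM1 lie furthest to the right in both panels (1.04 and 0.841 units at baseline, 1.11 for PROM1 and 1.07 for TSC22D1 after exercise), and no gene shown passed the adjusted threshold.

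Both comparisons with healthy subjects used the same 4 arrays. Of the genes at an unadjusted p under 0.05, 327 were higher in both and 79 lower in both, where independent lists would share 47.7 and 5.9. Unchanged patients simulated against shared healthy arrays shared 78.2 and 79.7 on average and up to 725 and 579 in 100 draws. Across genes, which are not independent replicates, the differences had a correlation of 0.838 and a covariance of 0.0241, against 0.75 and 0.0143 in simulation. With the healthy arrays divided into 2 and 2, the correlation was 0.188 on average (0.066 to 0.252 over 6 arrangements) and the covariance 0.00814, with 59.7 genes higher and 10.5 lower in both. The same patients stand on both sides of this division, so that levels particular to these people can still tie the 2 differences. For the genes shared in these smaller fits no number expected by chance was computed.

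Whether exercise moved transcripts back towards the healthy level was assessed by setting the exercise change against the baseline difference. Across genes the correlation was -0.227 and the covariance -0.00365, and 73% of the 888 genes with an unadjusted p under 0.05 at baseline changed in the opposite direction. Both quantities contain the baseline arrays, and simulation without any effect gave a correlation of -0.349 on average (-0.71 to 0.23) and a covariance of -0.00479. With separate patients for the 2 quantities (100 random divisions into 5 and 5), the correlation was 0.0139 on average (-0.21 to 0.313) and 52.6% of genes changed in the opposite direction.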

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

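The comparisons with other splits of the arrays were written before the results were seen. The tests of the share of sorted cells, the spike-in level, the changes of other cell types and the GAPDH measure were chosen after. The division into separate patients was planned, but the limits for reading it as a test of shared baseline arrays were written after. In 14 of 232 groups of values one array lay further from the others than Dixon's 95% limit, where chance alone gives about 1 in 20 groups, or 11.6. The arrays were not compared across these groups.

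Among single genes, the gap of the lowest array to the next, divided by the range of the group, was 0.624 for CD14 at baseline (0.217, next 1.22), 0.51 for THBS1 (0.375, next 0.88), 0.498 for VNN2 (0.584, next 1.04), 0.496 for CDKN1B (1.21, next 1.55) and 0.474 for ERCC6L2 (0.123, next 0.534), each at baseline. After exercise it was 0.672 for PRKCA (0.0208, next 0.709) and 0.527 for TNFRSF10B (0.381, next 1). In healthy subjects the highest array of MS4A1 stood apart with 0.86 (2.21, next 1.33).

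Among the list scores, the highest healthy array stood apart for the stem and progenitor cell list, with 0.86 (0.765, next 0.668), and for the lymphoid progenitor list, with 0.863 (1.61, next 1.32). At baseline the lowest array stood apart for the lymphoid progenitor list, with 0.501 (1.02, next 1.35), the basophil, mast cell and dendritic cell list, with 0.585 (0.62, next 0.974), the immediate early list, with 0.517 (1.08, next 1.45), and the glucocorticoid response list, with 0.626 (1.12, next 1.49).

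Chance was tested with 100 splits of the same arrays, the real one included. For genes at an unadjusted p under 0.05, 2 of 100 splits gave as many as the 888 of baseline against healthy (highest other 959). For after exercise against healthy, 4 of 100 gave as many as the 713 (highest other 829). Both shares lie under 0.05, but they are not adjusted over the 3 comparisons and rest on the same 4 healthy arrays. Chance is therefore not excluded for these counts. For the 436 genes of the exercise comparison the share was 17 of 100 (highest other 899), so that chance is not excluded there either. The counts of gene lists called by camera are within reach of chance in each comparison: 88 of 100 splits called as many as the 2 of baseline against healthy, 34 of 100 as many as the 5 of the exercise comparison and 76 of 100 as many as the 3 of after exercise against healthy, with a highest other count of 10 in each. Of the 99 other splits, 44, 43 and 50 called the progenitor list. At an adjusted p under 0.05, 4 of the 99 other splits of baseline against healthy gave genes (up to 31) and 5 of after exercise against healthy did (up to 3).

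The first pattern weighed is the higher progenitor list in patients at baseline. A lower share of sorted progenitors in the healthy arrays was tested on the assumption that the lists of the other cell types would be raised there alike. An excess of only some cell types would not do so, and the test does not cover that case. The group differences of 5 other types went both ways (monocyte -0.0741, T cell -0.0743, NK cell 0.161, platelet and megakaryocyte 0.256, and basophil, mast cell and dendritic cell -0.116), but their range of 0.371 is no wider than under permuted groups (exact permutation p = 0.457), so that this explanation cannot be told apart from others with 4 healthy arrays. A dimmer sample signal against the spike-ins is also open. With the spike-in level as a covariate the difference in list score went from 0.335 ± 0.167 to 0.234 ± 0.217 (SE, permutation p = 0.308). It was neither below 50% of its size nor past the threshold. The difference was not past the threshold without the covariate either (exact permutation p = 0.0749), so that the p with it says little about this explanation. Disease, the difference the design names, stays open as well and was not tested apart from these. The groups are different people, and age, sex and medication were not taken into account, so that they are not separated from disease. Chance stays open too: of the 99 other splits, 44 called the progenitor list.

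The second pattern is the higher progenitor list and lower monocyte, NK cell and platelet lists after exercise. If other cells in the sort had become fewer, patients whose progenitor score rose more would have lost more of the other types. Across the 10 patients the change of the progenitor score and the mean change of 5 other types had a correlation of -0.602 (permutation p = 0.0671; without the 2 farthest patients -0.458) and a rank correlation of -0.891 (p = 0.00116). The correlation of values misses the threshold while that of ranks passes it, so that a change in cell share may contribute and is not decided. For the platelet list alone the correlation was -0.0513 (p = 0.889), so that its fall does not follow the progenitor change in these patients. The scores are also bound by ranks within an array, so that a rise in some genes lowers others. A change in RNA integrity was tested with the GAPDH measure: the progenitor change went from 0.122 ± 0.123 to -0.0536 ± 0.127 at no change of GAPDH (sign-flip permutation p = 0.762). The progenitor change was not past the threshold before this either (exact sign-flip permutation p = 0.342), so that the p at no change says little about RNA integrity. Were RNA integrity the cause, the ACTB measure would relate to the progenitor change with the same sign as GAPDH. It related in the opposite direction (r = -0.684, against 0.63 for GAPDH), which goes against this explanation. The rank correlations were -0.842 for ACTB (permutation p = 0.00395) and 0.648 for GAPDH (p = 0.0501), both unadjusted. As the permutation p of the ACTB correlation of values was 0.105 when adjusted over 7 relations, the explanation is not decided. Exercise and time, which the design does not separate, stay open too. So does chance, as 43 of the 99 other splits called the progenitor list.

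The third pattern is that exercise changes ran opposite to the baseline differences from healthy subjects. Shared baseline arrays are enough to give this, as simulation without any effect gave a correlation of -0.349; with separate patients the mean correlation was 0.0139, against -0.227 in all patients, and it was negative in 47 of 100 divisions of the patients.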

How the results depend on the processing

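The spike-in covariate, progenitor covariate, normal scores, permuted array scores, median centring for the gene lists and left-out arrays that stand apart were chosen after seeing the data; the other alternatives were planned. Quantile normalization and log2(value + 32) were not run, as every array already holds the same values on a scale that is not linear. For changes below, the cause was not tested unless stated.

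Genes past the adjusted threshold in baseline against healthy numbered 0 in the reported fit, 12 at an adjusted p under 0.10 (a looser limit), 1 with all 24 arrays and a random patient block, 1 with arrays that stand apart left out, and 0 to 26 without 1 subject (26 without 1 healthy subject, 1 without 1 patient). After exercise against healthy there were 4 with array quality weights and 0 to 4 without 1 subject. For exercise the count was 0 in each alternative run, leaving out each patient included. At an unadjusted p under 0.05, a filter at the upper 25% of probe sets gave 507, 249 and 387 genes (fewer tested) for baseline, exercise and after exercise, in this order; the spike-in covariate gave 580 at baseline and 673 for exercise, no replicate block 285 for exercise, and the progenitor covariate 408 after exercise. Leaving out 1 subject gave 734 to 1016, 331 to 506 and 580 to 787.

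The lists called, 2, 5 and 3 in this order, became 0 in each comparison with estimated correlation, fry or permuted array scores. At baseline there were 5 without a filter and 4 with the mean of probe sets; for exercise 2 with the GAPDH covariate, 3 with normal scores, 2 with arrays that stand apart left out and 3 with no replicate block; after exercise 1 with the spike-in covariate and 5 with arrays that stand apart left out. Without 1 subject there were 1 to 4, 1 to 8 and 2 to 5.

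Adjusted p for the lists with estimated correlation was 0.904 for both baseline lists, 0.609 for the 5 exercise lists, and 0.891 (progenitor) and 0.893 (monocyte, pro-apoptotic) after exercise. With fry it was 0.268 (progenitor) and 0.187 (platelet) at baseline; 0.578 (progenitor), 0.565 (monocyte, NK cell) and 0.408 (platelet, cell cycle inhibitor) for exercise; 0.379 (progenitor) and 0.649 (monocyte, pro-apoptotic) after exercise. With permuted array scores it was 0.268 and 0.256 at baseline; 0.57 (progenitor, monocyte, NK cell) and 0.475 (platelet, inhibitor) for exercise; 0.3 and 0.682 (monocyte, pro-apoptotic) after exercise. With the spike-in covariate it was 0.0927 for platelet genes at baseline, and 0.118 (monocyte) and 0.0864 (pro-apoptotic) after exercise. With the GAPDH covariate the exercise lists gave 0.826 (progenitor, reversed), 0.0871 (monocyte), 0.991 (NK cell), 0.42 (platelet) and 0.467 (inhibitor), and pro-apoptotic genes after exercise 0.0778. With arrays that stand apart left out, exercise gave 0.13 (progenitor), 0.286 (monocyte), 0.259 (NK cell) and 0.305 (inhibitor), and pro-apoptotic genes 0.0757. Normal scores gave 0.08815 (NK cell), 0.0544 (inhibitor) and 0.0561 (pro-apoptotic); no replicate block 0.11 (NK cell) and 0.0621 (inhibitor); the mean of probe sets 0.123 (inhibitor); and no filter 0.0593 (pro-apoptotic).

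Without 1 subject the adjusted p ran from 2.12e-05 to 0.0105 (progenitor) and 1.92e-05 to 0.0964 (platelet) at baseline; for exercise from 1.17e-08 to 0.0988 (progenitor), 8.28e-06 to 0.43 (monocyte), 1.51e-06 to 0.287 (NK cell), 0.000342 to 0.0961 (platelet) and 0.00549 to 0.145 (inhibitor); after exercise from 6.02e-14 to 1.665e-07 (progenitor), 2.44e-07 to 0.0615 (monocyte) and 0.00782 to 0.41 (pro-apoptotic).

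With ACTB in place of GAPDH the 3' to 5' difference was -0.320 at baseline (reversed), 0.0087 for exercise and -0.3115 after exercise (reversed). The correlation of exercise changes with baseline differences was 0.0139 with split patients (reversed), since separate patients no longer share baseline arrays. Of 1639 values of named genes under alternatives, 3 reversed: VCAN at 0.0591 and CLEC7A at 0.00236 with the progenitor covariate, and TNFSF10 at 0.006315 with the mean of probe sets. Another 12 newly passed the threshold. Many of the 1639 could not reverse, as the variance models and the filters leave a gene's own difference unchanged. The total also includes the fits without 1 subject, and the genes had been picked for a small p. The count of 3 is therefore no measure of stability. Named differences moved by over 1.5 times or turned in 6 of 18 genes at baseline with the mean of probe sets. Only PARVB, STAT3, SRPK2, SERPINB9, SP100, ELP2 and ANGPT1 had several probe sets above the filter there, so that the other genes could not move. Of these genes with several probe sets, all but SP100 became smaller by over 1.5 times. For exercise they did so in 19 of 27 with array quality weights and 12 with the GAPDH covariate. With the progenitor covariate it was 8 of 17 after exercise, 4 of 24 for exercise and 0 of 15 at baseline. Whether dim probe sets limit precision was not tested, and the low end of the score has no known scale.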

Other observations

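Among lists that camera did not call between baseline and healthy, the proteasome, antioxidant and oxidative phosphorylation lists had a permutation p of their array scores below 0.05. The permutation does not set a list against other genes, and the median difference over all 7264 genes was 0.0434 units higher in patients. Camera, which does, gave adjusted p = 0.318, 0.431 and 0.462, in this order. Of 23 proteasome genes 16 were higher in patients (mean difference 0.0908 units, in 10 of 10 patients; exact permutation p = 0.00999, adjusted p = 0.242), of 18 antioxidant genes 13 (0.102, 10 of 10 patients; p = 0.026, adjusted p = 0.242) and of 32 genes of oxidative phosphorylation 24 (0.0686, 9 of 10 patients; p = 0.029, adjusted p = 0.242). Of 36 cytosolic ribosomal protein genes 29 were higher (0.123; exact permutation p = 0.134; camera adjusted p = 0.0734). With exercise the oxidative phosphorylation list had 24 of 32 members lower (-0.0487, in 8 of 10 patients; exact sign-flip permutation p = 0.152, adjusted p = 0.475; camera adjusted p = 0.0818). Between after exercise and healthy, the permutation p was 0.698 for oxidative phosphorylation, 0.306 for proteasome and 0.0959 for antioxidant genes. None of these lists passed the correction.

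Levels of cell type genes in the sorted cells were, in healthy subjects (n = 4), patients at baseline (n = 10) and after exercise (n = 10), 3.19 ± 0.434, 2.85 ± 0.581 and 2.82 ± 0.471 (SD) for the monocyte gene LYZ, 1.38 ± 0.247, 1.38 ± 0.477 and 1.26 ± 0.303 for CD14, 1.23 ± 0.666, 1.29 ± 0.257 and 1.29 ± 0.365 for the T cell gene CD3D, 0.759 ± 0.453, 0.734 ± 0.402 and 0.701 ± 0.454 for CD3G, and 2.62 ± 0.803, 1.86 ± 0.885 and 2.08 ± 0.979 for the haemoglobin gene HBB. They were 0.669 ± 0.376, 0.728 ± 0.401 and 0.865 ± 0.495 for HBD, 2.15 ± 0.347, 2.15 ± 0.25 and 2.08 ± 0.265 for the endothelial and leukocyte gene PECAM1, 0.361 ± 0.402, 0.728 ± 0.443 and 0.719 ± 0.385 for ROBO4, and 0.525 ± 0.345, 0.721 ± 0.355 and 0.967 ± 0.227 for KIT.

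The relations between the changes of the progenitor score and of other measures in the 10 patients were chosen after the results were seen. The correlation was -0.587 with the monocyte score (permutation p = 0.0751), -0.438 with the T cell score (p = 0.208), -0.605 with the NK cell score (p = 0.0625), -0.0513 with the platelet score (p = 0.889), -0.723 with the spike-in level (p = 0.0183), 0.63 with the GAPDH measure (p = 0.0517) and -0.684 with the ACTB measure (p = 0.0316). Adjusted over the 7 relations, the lowest p of these correlations was 0.105. Among the rank correlations, which were not adjusted, the smallest permutation p was 0.00395, for the ACTB measure (-0.842). The next was 0.0492, for the spike-in level (-0.648). Without the 2 patients farthest from the centre the spike-in correlation was -0.495 and the ACTB correlation -0.65.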
